A study of Rattus norvegicus with 16 samples.

How the data were processed

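Genomic DNA of 16 renal cell carcinomas from male Jcl:SD rats was compared with DNA of normal kidney cortex on Agilent 180K rat genome CGH arrays, 1 array per tumour. Per the labels, each array carried tumour DNA in Cy5 and normal cortex DNA in Cy3, both given the same genotype, and no array had the dyes exchanged. The labels do not say how many animals gave the normal DNA, or whether the arrays of a genotype shared it. Groups were taken from the genotype in the labels, with 8 wild-type and 8 Brca1+/- tumours, and replicate numbers follow deposit order and pair no animals. The labels give each tumour its own name, but do not state outright that each came from a different rat, so p-values measure the spread between these samples.

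The arrays were read with Agilent Feature Extraction 10.7, per the submitters' processing notes. The deposited values are log ratios, taken as log2 ratios of tumour over normal DNA, for 174012 features on each array with 0 missing values. The values ran from -7.93 to 8.64, which is wider than a scanner can give on a log10 scale. A natural log could not be ruled out from the values, so sizes in log2 units rest on that reading. The direction was taken from the dyes in the labels, with Cy5 over Cy3 as the usual form of the software. Array medians as deposited lay between -0.03 and 0.01, so the values had been centred before deposit. The kind of centring, the dye normalization, the genome build and the probe annotation are not given in the sources used here. Control features and signals over background were not analysed here, and the number of arrays limits the precision.

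The deposited values carry feature numbers from 23 to 180858, and no table used here pairs these numbers with genes or genome positions. Neighbouring feature numbers were nearly uncorrelated on every array, with a highest lag-1 autocorrelation of 0.02, so feature order could not stand for genome order. For this reason the steps planned on genome order or on genes were not run. These were segmentation and segment boundaries, shares over autosomes alone, differences per chromosome, recurrence by circular shift, the fixed gene lists, and the joint occurrence of Met gain and Cdkn2a loss. The fallback fixed before the data were examined was used, which calls single measured items by the same limits, here features. The rule for named genes asked for Brca1, Cdkn2a, Cdkn2b and Met first, then list members altered in at least 6 of 16 tumours, then the genes altered most often and those differing most between genotypes. It could not be applied, and 2 features per direction with the lowest adjusted p are given by number.

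Each array was centred on its median, with no loess or quantile step. A feature was called gained at a log2 ratio of 0.2 or more, lost at -0.2 or less, amplified at 0.8 or more and deeply deleted at -1.0 or less. The share of features past each limit was computed per tumour. Single features carry more noise than segments, so these shares include features pushed past a limit by noise. To gauge this, a normal curve was fitted to the main peak of each array (the core), and the share it puts past each limit was subtracted in an alternative. On simulated arrays with 7% of features gained, 10% lost and 2% amplified, the calls gave 11.3% gained and 13.6% lost at a noise SD of 0.12. At a noise SD of 0.36 they gave 31.3% gained, 31.6% lost and 3.99% amplified. Subtracting the core gave 6.63% gained and 9.70% lost at the lower noise and 3.02% and 4.29% at the higher, so the subtraction removed true changes where noise was high.

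Shares were compared between genotypes by an exact two-sided permutation test over all 12870 splits of the 16 tumours, with Benjamini-Hochberg adjustment over the 6 measures. Gained and lost shares were set against each other within tumours by an exact sign-flip test. For recurrence, the number of features altered in a given number of tumours was set against the number for independent tumours with the same shares. Call frequencies per feature were compared by Fisher's exact test. Log2 ratios per feature were fitted with limma 3.58.1 in R 4.3.3, with a mean per genotype, eBayes and Benjamini-Hochberg adjustment at 0.05. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The limma step was tested on simulated data with 174012 features and 50 changed features per size. It recovered 34% of those changed by 0.5, 88% at 1, 96% at 2 and 100% at 4, with 11 false calls.

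The tests between genotypes, within tumours and per feature were set in advance. The resemblance of profiles within a genotype and the counts of features altered in at least 3 of 8 tumours were chosen after seeing the data. Recurrence was planned with a circular shift along the genome, and the comparison with independent tumours took its place once no order could be had. For resemblance, Pearson's r was computed across features after limiting ratios to 1.5 in size, and the mean r of pairs within a genotype was set against that of mixed pairs over all splits. Features are not independent replicates in these correlations. Alternatives set in advance were limits of 0.1 and 0.3, the mode as centre, values as deposited, limits scaled by the 99th percentile of each array, limma array weights, the label code as a random block and each tumour left out in turn. Alternatives added after seeing the data were limits of 0.5 and 1.5, the core, leaving out both Brca1+/- replicates 1 and 2, leaving out features past 0.8 the same way on all 8 arrays of a genotype, and tests within label codes or within sets of 4 arrays in deposit order. The code stands before the genotype letter in the tumour's label, and its meaning is not stated there. For 100 random splits of the 16 arrays the limma fit was repeated.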

Results

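Copy number profiles were obtained from renal cell carcinomas of rats given ferric nitrilotriacetate (Fe-NTA), an iron chelate that drives oxidative damage in the kidney. The rats were wild-type or Brca1+/-. Brca1 is a tumour suppressor needed for repair of DNA double-strand breaks by homologous recombination. Injections into the peritoneum began at 5 weeks of age, with doses of 5, 7 and 10 mg iron per kg. Of 20 wild-type and 19 Brca1+/- rats, 17 of each genotype developed a carcinoma, and 8 tumours per genotype were profiled. Each array gave the log2 ratio of tumour over normal kidney cortex DNA for 174012 features. The comparison of genotypes asks whether losing 1 Brca1 allele alters the copy number changes of these tumours. Because no table used here places features in the genome, amounts and patterns of change are described without gene names.

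Gains and losses of DNA were found in both genotypes, in amounts that differed between tumours of 1 genotype. The called altered share of features ran from 15.4% in wild-type replicate 4 to 61.3% in Brca1+/- replicate 1. The width of each array's main peak entered these shares, and the order changed once a normal curve of that width was subtracted, as given below. Amplified features, at a log2 ratio of 0.8 or more, made up 0.441% of features in wild-type replicate 4 and 5.33% in Brca1+/- replicate 7. Features at a ratio of 2 or more made up 1.63% in Brca1+/- replicate 7 and 1.09% in wild-type replicate 1, against 0.0690% in wild-type replicate 4. A separate peak of losses stood below the main peak in 4 wild-type and 2 Brca1+/- tumours. It lay between -0.64 and -0.48 from the main peak in the wild-type tumours and at -0.60 and -0.58 in the Brca1+/- tumours. The features below the valley between the peaks made up 25.8% of features in wild-type replicate 8 and 21.8% in Brca1+/- replicate 3. The width of the main peak also differed between arrays. Its fitted SD was 0.12 in wild-type replicate 4 and 0.36, 0.31 and 0.30 in Brca1+/- replicates 1 and 2 and wild-type replicate 2. A normal curve of that width alone puts 25.7% of features past the gain limit in Brca1+/- replicate 1 and 4.44% in wild-type replicate 4, and 28.3% past the loss limit in the former. With this core subtracted, the altered share was 7.31% in Brca1+/- replicate 1, 6.42% in wild-type replicate 4 and highest, at 32.9%, in Brca1+/- replicate 3. The breadth of Brca1+/- replicates 1 and 2 was partly shared (r = 0.667 across features), so it was not all independent noise. The subtraction also removes true changes on broad arrays, so the altered share of Brca1+/- replicate 1 stays uncertain.

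**Figure D1:**
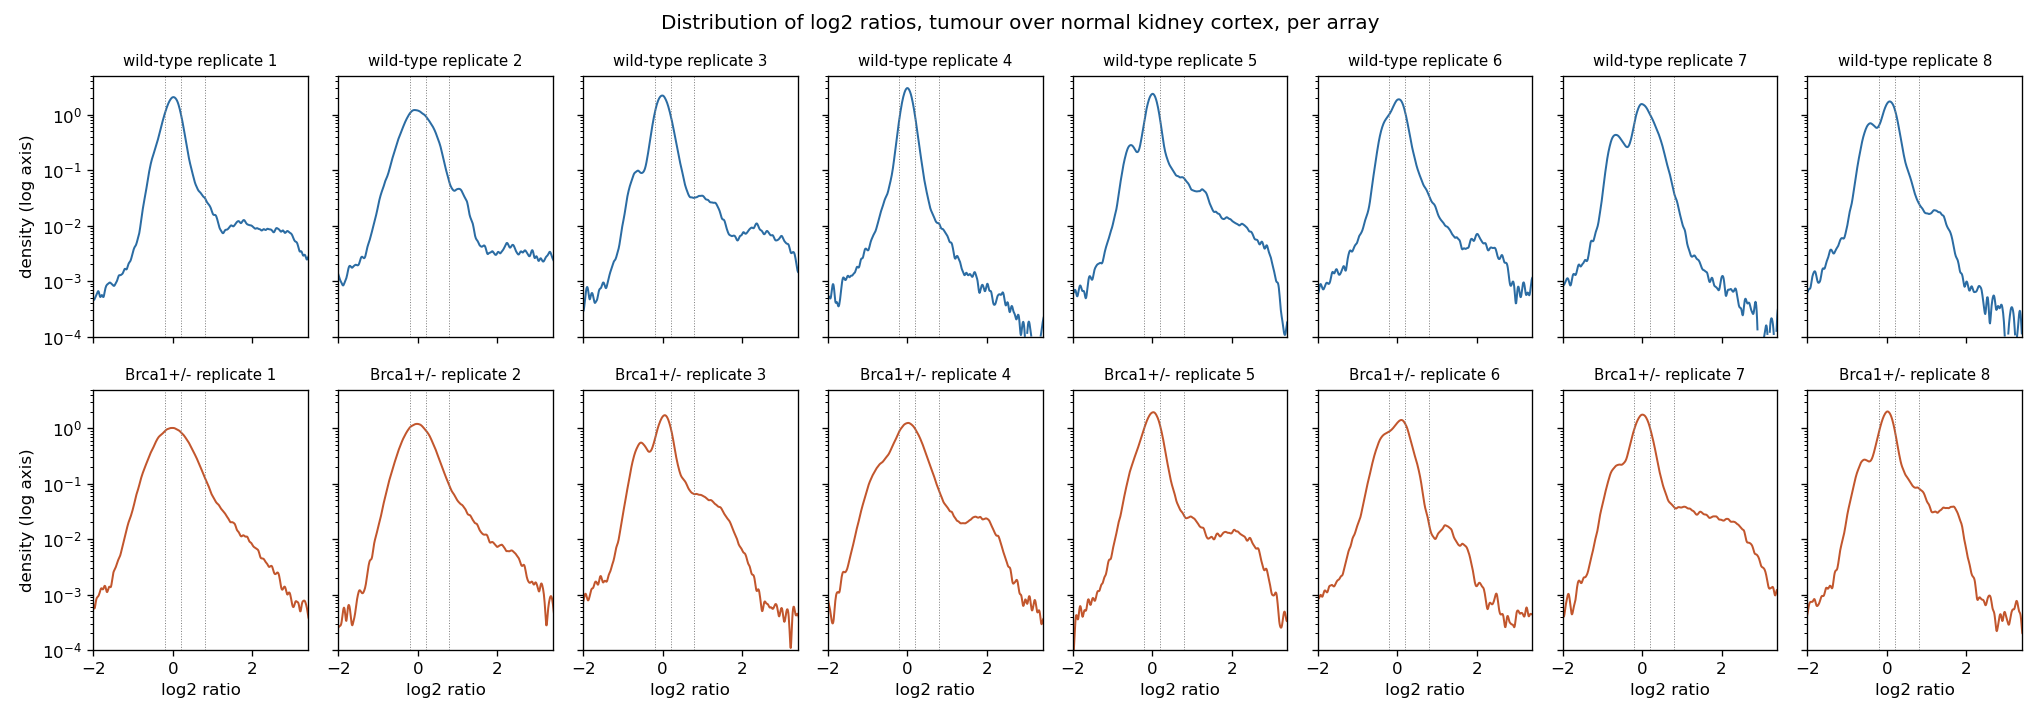
Density of log2 ratios (tumour over normal kidney cortex, x axis) of the 174012 features on each array, on a log axis, with wild-type tumours in the upper row and Brca1+/- tumours in the lower. Dotted lines mark -0.2, 0.2 and 0.8; 6 tumours show a separate lower peak between -0.64 and -0.48 from the main peak, and wild-type replicate 4 has the narrowest distribution (SD 0.25).

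Brca1+/- tumours carried more amplified features than wild-type tumours, but the difference did not pass after adjustment for the 6 measures compared. The amplified share was 4.01% ± 1.27 (SD, n = 8) in Brca1+/- and 2.25% ± 1.40 (SD, n = 8) in wild-type tumours, a 1.78-fold higher mean (exact permutation p = 0.0236, two-sided; adjusted p = 0.127). It was above the wild-type median in 7 of 8 Brca1+/- tumours. The gained share was 22.6% ± 5.43 against 17.2% ± 6.13 (exact permutation p = 0.0847, adjusted p = 0.127, SD, n = 8 each). The lost share was 25.4% ± 4.44 against 19.6% ± 7.26 (exact permutation p = 0.0746, adjusted p = 0.127). Gains and losses together came to 48.0% ± 9.33 in Brca1+/- and 36.8% ± 12.6 in wild-type tumours (exact permutation p = 0.0650, adjusted p = 0.127). Deeply deleted features made up 0.593% ± 0.400 and 0.370% ± 0.138 (exact permutation p = 0.143, adjusted p = 0.171), and without Brca1+/- replicate 4 the difference fell from 0.223 to 0.0973 percentage points (exact permutation p = 0.285). None of the 6 differences passed after adjustment. For the 12 tumours whose label codes hold both genotypes, differences within each of the 4 codes were averaged, weighted by the code's number of tumours. This weighted difference in amplified share was 0.707 percentage points (exact permutation p = 0.486, 72 splits within codes), against an unweighted 1.76 over all 16 tumours. The gained difference there was 1.82 (exact permutation p = 0.625), against 5.37 over all, the lost 5.40 (exact permutation p = 0.125) and the altered 7.22 (exact permutation p = 0.319). Code C5, which has the largest weight, holds 1 Brca1+/- tumour, replicate 6, which had the lowest amplified share of its genotype (1.42%). Without Brca1+/- replicates 1 and 2 the gained difference was 3.08 (exact permutation p = 0.308). The amplified difference was 1.64 without Brca1+/- replicates 1 and 2 (exact permutation p = 0.0589), 0.677 at a limit of 1.5 (exact permutation p = 0.0660) and 0.780 with limits scaled to each array (exact permutation p = 0.169). The scaled limits rise with an array's largest ratios, amplified features included, which by itself can shrink this difference. With the core subtracted, the gained share was 6.25% ± 2.65 in Brca1+/- and 6.19% ± 3.66 in wild-type tumours (exact permutation p = 0.974), and the amplified share 3.81% ± 1.26 and 2.22% ± 1.38 (exact permutation p = 0.0325). Each set of 4 arrays in deposit order holds 2 tumours per genotype, and the first holds the 3 broadest arrays. Within these sets, a block chosen after seeing the data, the exact permutation p was 0.0664 for gained, 0.0957 for lost, 0.0725 for altered, 0.0478 for amplified and 0.171 for deeply deleted shares, with the differences unchanged.

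**Figure D2:**
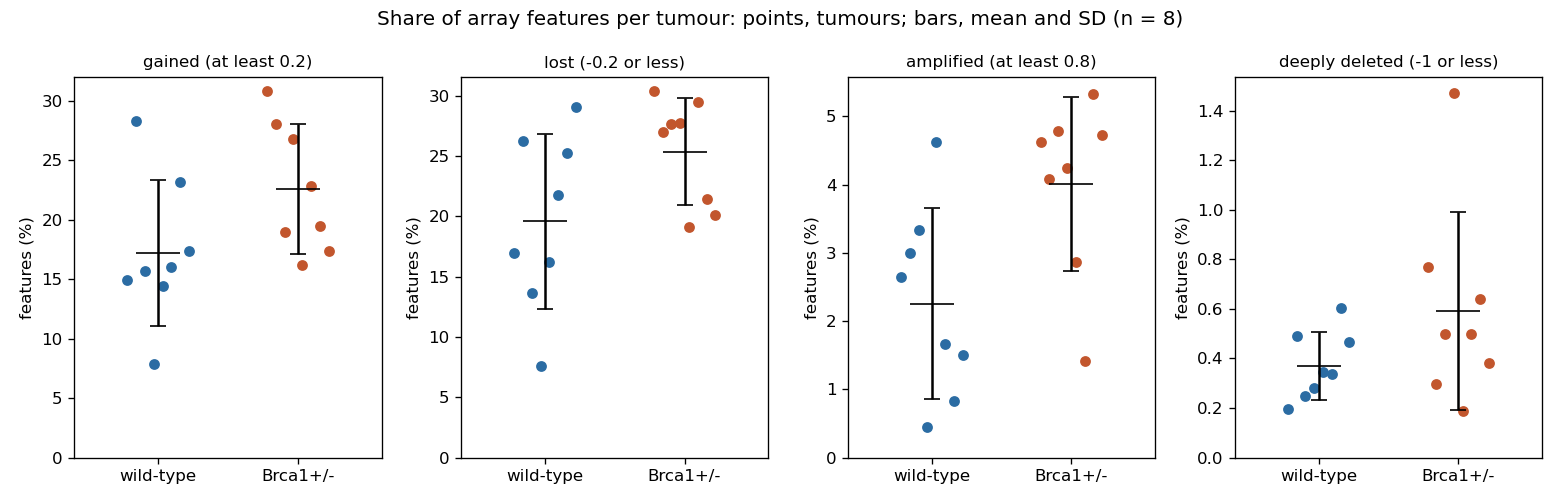
Percent of features (y axis) gained, lost, amplified and deeply deleted in each tumour of the 2 genotypes; points are tumours, and bars give the mean and SD (n = 8 per genotype). Amplified shares run from 0.441% to 4.62% in wild-type and from 1.42% to 5.33% in Brca1+/- tumours, and 1 Brca1+/- tumour stands apart at 1.47% deeply deleted features.

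Over all 16 tumours, features past the loss limit outnumbered those past the gain limit, on arrays centred on their medians. The gained share minus the lost share was -2.57 ± 3.88 percentage points (SD, n = 16; exact sign-flip permutation p = 0.0126), with more lost than gained features in 11 of 16 tumours. It was -2.78 ± 3.37 in Brca1+/- tumours (SD, n = 8; exact sign-flip permutation p = 0.0469), with more losses in 6 of 8. In wild-type tumours it was -2.37 ± 4.55 (SD, n = 8; exact sign-flip permutation p = 0.219), with more losses in 5 of 8. The balance did not differ detectably between genotypes (difference -0.414 percentage points, exact permutation p = 0.842, adjusted p = 0.842), with -4.83 for the mode as centre (exact permutation p = 0.391) and -3.58 within label codes (exact permutation p = 0.0972). Because arrays were centred on their medians, this balance depends on the centre, and with the mode as centre the value over all tumours was -5.40 (exact sign-flip permutation p = 0.0645), so a surplus of losses is not established. With the values as deposited it was -4.36 (exact sign-flip permutation p = 6.1e-05). In that form the wild-type balance also passed (-3.68, exact sign-flip permutation p = 0.0156). The Brca1+/- call was lost with a limit of 0.3 (-3.23, exact sign-flip permutation p = 0.0703) and when any of replicates 3 to 8 was left out (-3.05 to -1.93).

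The same features passed a limit in many tumours. Of all features, 1630 were gained in at least 13 of 16 tumours, where independent tumours with the same shares would give 0.026. Losses in at least 14 of 16 tumours were seen at 513 features (0.0063 for independent tumours). Amplification in at least 7 of 16 tumours was seen at 2779 features (0.033 for independent tumours) and deep deletion in at least 5 at 605 (0.0015 for independent tumours). The highest number of tumours was 16 for amplification and 15 for deep deletion. These counts take features as separate, although features of 1 region change together, and a feature unlike the reference DNA on every array counts as recurrent too. Without dye exchange, so would a feature with a dye effect. Gains in at least 3 of 8 tumours were seen at 50824 features in Brca1+/- and 31851 in wild-type tumours (exact permutation p = 0.0452), where independent tumours with the same gained shares would give 45517 and 24844, a difference no smaller than the one observed. For losses the counts were 59863 and 44829 (exact permutation p = 0.209), for amplification 6614 and 4480 (exact permutation p = 0.324), and for deep deletion 561 and 620 (exact permutation p = 0.677), and these 4 p-values were not adjusted. Amplification in at least 3 of 8 tumours of both genotypes was found at 2650 features, against 170 for independent lists. No single feature passed adjustment by Fisher's exact test of call frequency, for gains, losses, amplification or deep deletion, but this test could hardly call one. With 8 tumours per genotype its smallest p is 0.000155, and a call would need many features to reach it together. Features did reach it, altered in all 8 tumours of 1 genotype and none of the other. The lowest adjusted p by Fisher's exact test was 0.160 for gains, 0.231 for losses and 0.297 for amplification. At an unadjusted p under 0.05 there were 5114, 5619, 574 and 204 features.

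Tumour and normal DNA differed in mean ratio at 13158 features in wild-type and 35579 in Brca1+/- tumours by limma. In wild-type tumours 7086 of these were higher and 6072 lower in the tumour, and in Brca1+/- tumours 16274 were higher and 19305 lower. With the mode as centre, the split in Brca1+/- tumours was 11650 higher and 22977 lower. Both genotypes were higher at 2698 features and lower at 2334, against 663 and 674 for independent lists, and they went opposite ways at 305. Over all 16 tumours, 44067 features were called. With limma array weights the order of the genotypes turned, with 30638 features in wild-type and 27328 in Brca1+/- tumours. Without Brca1+/- replicates 1 and 2 the numbers were 13951 and 16208, the latter from 6 tumours. Leaving out 1 wild-type tumour lowered the wild-type number to 5698 (replicate 8), 5803 (replicate 6), 6349 (replicate 1), 7719 (replicate 5), 7768 (replicate 2) or 8576 (replicate 7), and without Brca1+/- replicate 1 the Brca1+/- number was 23702. Without dye exchange, a dye effect at a feature would enter these counts.

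The ratio itself differed between genotypes at 1487 features by limma, with 806 higher and 681 lower in Brca1+/- tumours. With the mode as centre the counts were 674 and 767. Of the 1487, 535 differed by at least 1 on the log2 scale (430 higher and 105 lower in Brca1+/- tumours), and 168 by at least 4. The other 952 differed by less than 1, with 376 higher and 576 lower. Feature 36098 had a mean ratio of 6.12 ± 0.33 in Brca1+/- and 0.05 ± 0.28 in wild-type tumours (SD, n = 8 each; limma difference 6.07, SE 0.15, adjusted p = 9.7e-14). Feature 123726 was higher in Brca1+/- tumours by 5.22 (SE 0.15, limma adjusted p = 1.2e-12). Feature 63696 had a mean ratio of 3.5 ± 0.39 in wild-type and 0.08 ± 0.49 in Brca1+/- tumours (SD, n = 8 each; limma difference -3.41, SE 0.20, adjusted p = 2.2e-08), and feature 46664 differed by -2.52 (SE 0.17, limma adjusted p = 1.4e-07). At 1081 features the 8 tumours of 1 genotype all lay above the 8 of the other, where chance gives 0.0155% of features, or 27.0. The number called fell to 827 without Brca1+/- replicates 1 and 2 and to 906, 969 and 970 without wild-type replicate 4, wild-type replicate 6 or Brca1+/- replicate 2 alone, and rose to 2568 with limma array weights. The array weights turned the split, with 1091 higher and 1477 lower. Leaving out Brca1+/- replicate 4 did so too (958 and 1262), while without any other single tumour more features were higher than lower. With sets of 4 arrays in deposit order as a block it was 1620. Normal DNA of the same genotype stood on each array, so genotype and reference DNA changed together.

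**Figure D3:**
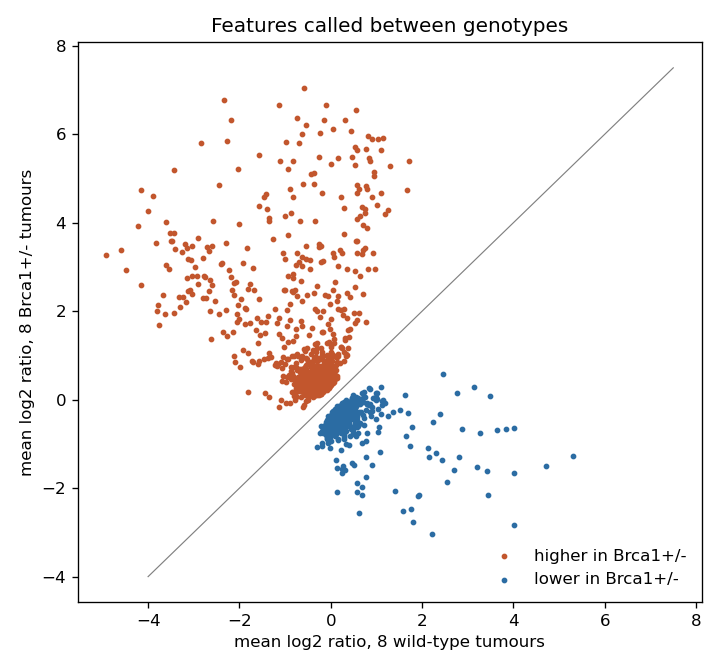
Mean log2 ratio of each of the 1487 features called between genotypes, in the 8 wild-type tumours (x axis) and the 8 Brca1+/- tumours (y axis), with the line of equal means. The features higher in Brca1+/- (806) and lower in Brca1+/- (681) fall on either side of the line, and 168 of them differ by at least 4.

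Whole profiles resembled each other more within a genotype than between genotypes. The mean correlation across features was 0.344 for wild-type pairs, 0.290 for Brca1+/- pairs and 0.20 for mixed pairs. The mean within genotypes exceeded that of mixed pairs by 0.117 (exact permutation p = 0.000155, one-sided, the smallest the 12870 splits can give). The highest correlation was 0.667, between Brca1+/- replicates 1 and 2. In the plane of these 2 tumours the features formed 1 smooth ellipse, whereas in the 2 other planes drawn, of tumours with a lower peak, they fell into separate groups.

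**Figure D4:**
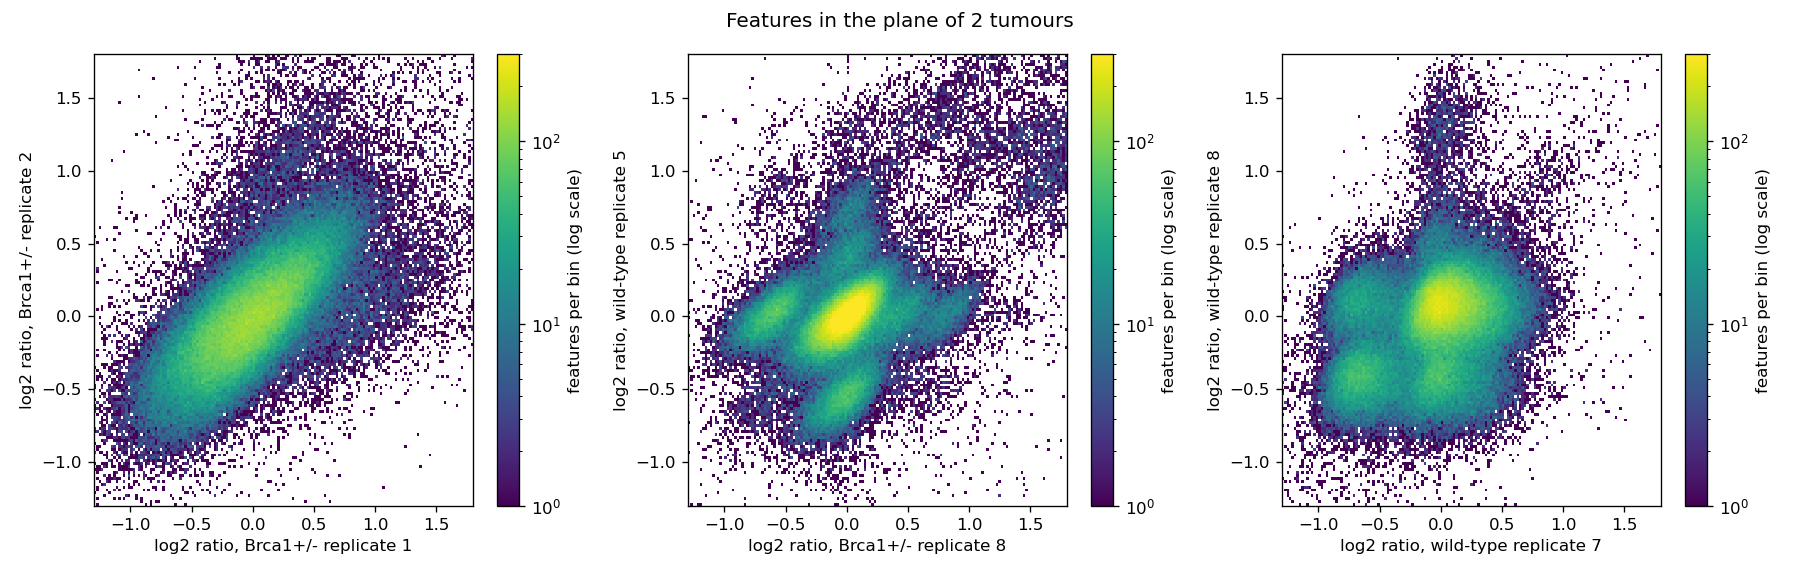
Number of features (colour, log scale) by log2 ratio in the planes of 3 pairs of tumours, in bins of equal width. Brca1+/- replicates 1 and 2 form 1 ellipse (r = 0.667 across features), while Brca1+/- replicate 8 against wild-type replicate 5 and wild-type replicate 7 against replicate 8 show separate groups of features at the lower peaks (-0.58, -0.54, -0.64 and -0.48 from the main peak of each tumour).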

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

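The tests of leaving out 2 arrays, of leaving out features past 0.8 on all arrays of a genotype, of the core, of label codes, of the lower density peaks, of features gained in at least 3 of 8 tumours, of wild-type replicate 4 and of the splits for ratios against 0 were chosen after the results were seen. Deep deletion stood apart in Brca1+/- replicate 4, at 1.47% of features, with a gap to the next tumour of 0.548 of the range of the 8 tumours. Of 14 groups of values tested for such gaps, this was 1, where chance gives 0.7. Without this tumour the difference in deep deletion was 0.0973 (exact permutation p = 0.285), against 0.223 with it. The number of features gained in at least 3 of 8 tumours was higher by 18973 in Brca1+/- than in wild-type tumours by the exact permutation test (p = 0.0452). The gained shares alone, with independent tumours, would give 45517 and 24844 such features, a difference no smaller than the one observed. The difference in gained share itself with the core subtracted was 0.0505 (exact permutation p = 0.974).

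The share of amplified features was higher by 1.76 percentage points in Brca1+/- tumours, and without features past 0.8 the same way on all 8 arrays of a genotype, as unlike reference DNA would give, it was higher by 1.71, but these 339 features are 0.195% of all, too few for the test to decide. The tables argue against broadened distributions of Brca1+/- replicates 1 and 2 as the whole cause, since the difference was 1.59 with the core subtracted (exact permutation p = 0.0325), the core giving 0.190 points of the Brca1+/- mean through these arrays, and 1.64 without both (exact permutation p = 0.0589, from fewer tumours). The core was made the criterion after these values were seen, and a first one on the p without both arrays left the question open. Limits scaled to each array gave 0.780 (exact permutation p = 0.169), but these limits rise with an array's own amplified features, so this value does not decide it. More normal cells in wild-type tumours may lower their ratios, but a lower peak was found in only 4 wild-type and 2 Brca1+/- tumours (mean position different by 0.0225), too few to decide. An effect of the Brca1 allele on amplification stays open as a hypothesis, with adjusted p = 0.127 and a difference of 0.707 within label codes.

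The ratio differed between genotypes at 1487 features, and chance is unlikely to account for their number. Of 100 splits of the 16 arrays only 1, the real one, gave as many, and the highest other gave 208. The smallest share that these splits can give is 1 of 100. A candidate explanation is that the normal DNA of the 2 genotypes differed in germline copy number at these features. In wild-type replicate 4, the tumour with the smallest altered share, the ratio was a median of 1.17 of the mean of the other 7 wild-type tumours at 396 features differing by at least 1 and 0.845 at 176 differing by less, among features called without it whose mean in those 7 was at least 0.3 in size (80 and 254 others fell below). At features not called but matched for mean and SD in those 7 it was 0.849 and 0.617, and a first criterion, 0.2 above the matched features, favoured different reference DNA. It was replaced after these values were seen by one on the lower quartile of the called features (0.590 and 0.498). Under that one the test does not decide. At 216 called features with a Brca1+/- mean of at least 2 and a wild-type mean under 1, the median SD between Brca1+/- tumours was 1.43 (median of the means 3.32). It was 1.72 at 111 features not called with such a Brca1+/- mean (median 2.50). The small SDs of the features named in Results are thus not typical of the large differences. Reference DNA, germline differences of the rats and tumour changes that follow genotype cannot be told apart.

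For the number of features called against 0, 4 of 100 splits gave a difference between groups as large as the real 22421 (the real one included), and the highest other split gave 27542, above the real value. The order of the genotypes turned with array weights (30638 in wild-type and 27328 in Brca1+/- tumours), so the difference is not read as one of genotype.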

How the results depend on the processing

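The alternatives with limits of 0.5 and 1.5, the core, shared features, label codes, sets of 4 arrays in deposit order and both Brca1+/- replicates 1 and 2 left out were chosen after seeing the data. Of 387 recomputed values, 322 kept their direction and side of the threshold or stayed within 1.5 times a count. Where a value changed, the cause was not tested, except that smaller counts of tumours or features follow from fewer arrays. Differences between genotypes are in percentage points, and the threshold is an unadjusted exact permutation p of 0.05. With a limit of 0.5 the gained difference was 3.06 (exact permutation p = 0.0291) and the altered 5.91 (exact permutation p = 0.0476), both now past the threshold, and the balance turned to 0.207. With limits of 1.5 the amplified difference was 0.677 (exact p = 0.0660) and deep deletion turned to -0.0412. With the mode as centre the lost difference was 7.93 and deep deletion 0.317, and with values as deposited the lost difference was 6.16, each now past the threshold. The gained difference fell to 3.10 with the mode (exact permutation p = 0.456). With limits scaled to each array the amplified difference was 0.780, deep deletion turned to -1.45, and the gained, lost and altered differences shrank to 0.798, 1.86 and 2.66. With the core subtracted these 3 were 0.0505, 1.93 and 1.98. The amplified difference was 1.64 without Brca1+/- replicates 1 and 2 and 0.707 within label codes, not past the threshold. Leaving out each tumour in turn gave 4.03 to 6.96 for gained (past the threshold in 1 of 16 runs), 4.07 to 7.14 for lost (3 runs), 8.10 to 13.7 for altered (5 runs), -1.75 to 0.433 for the balance, 1.5 to 2.13 for amplified (all 16 runs) and 0.0973 (without Brca1+/- replicate 4) to 0.280 for deep deletion (1 run). The balance turned without wild-type replicate 2 (0.215) or 3 (0.211) and Brca1+/- replicate 3 (0.433) or 6 (0.135). Gained minus lost share was -3.68 in wild-type tumours as deposited (exact sign-flip permutation p = 0.0156, now past the threshold), while the calls were lost at -3.23 in Brca1+/- tumours with a limit of 0.3 and -5.40 in all with the mode. With each tumour left out it was -3.00 to -1.03, -3.33 to -1.93 and -2.88 to -1.96 in wild-type, Brca1+/- and all tumours. The least number of tumours for recurrence follows from the shares. At a limit of 0.1 it rose to 16 of 16, with 471 features gained and 246 lost. With each tumour left out, 972 to 1202 were gained in at least 13 of 15, and 257 (at least 14, without wild-type replicate 4) to 836 (at least 13, without wild-type replicate 3) were lost, with amplification at 2083 to 2720. Features called between genotypes numbered 2568 with array weights, 827 without both replicates and 906 to 2220 with each tumour left out. Against 0, wild-type tumours had 30638 with array weights and 5698 to 15785 with each left out, and Brca1+/- tumours 16208 without both replicates and 23702 to 37343 with each left out. The label code as a random block gave 1428 features between genotypes. The excess of resemblance was 0.106 to 0.133 with each tumour left out. The label codes and sets are blocks, not pairs. No paired analysis was possible because replicate numbers follow deposit order and pair no animals. Not run, for lack of positions or genes per feature, were the segmentation penalties, autosomes only, segment means, gene means or genes with at least 3 probes, and all alternatives for segment boundaries, gene lists, chromosomes and Met with Cdkn2a.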

Other observations

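The lower peaks gave an estimate of how many cells carried the losses. If the features of that peak had lost 1 of 2 copies and the values are log2 ratios, the peaks correspond to 56.6% to 71.7% of cells in the 4 wild-type tumours and to 68.0% and 66.2% in Brca1+/- replicates 3 and 8. Wild-type replicate 4, the tumour with the smallest altered share, had 768 amplified features in all, and 493 of them were among the 2720 features amplified in at least 7 of the other 15 tumours. Of its 486 deeply deleted features, 292 were among the 555 deeply deleted in at least 5 of the other 15. At these 555 features its median ratio was -1.08, against a 1st percentile of -0.502 over all its features. At the 2720 features its median ratio was 0.0662. With so few of its features called, the missing calls at the rest of these lists do not show what the lists are. The 2 medians do not depend on its calls, but they come from 1 array, and no cause is drawn from them. Features at 0.8 or more on all 8 arrays of a genotype numbered 234 in Brca1+/- and 112 in wild-type tumours, of which 57 and 13 were at 2 or more on all 8.

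The test among features near the centre, and the comparison of resemblance itself, were chosen after the data were seen. Profiles resembled each other more within a genotype, with a mean correlation higher by 0.117 than between genotypes. The features called as different between genotypes are not the whole source, since the excess without them was 0.0796, the exact permutation p staying at 0.000155, the smallest possible. Changes past 0.3 in size are not the whole source either. Among 5702 features within 0.3 of the centre on all 16 arrays the excess was 0.0956 (exact permutation p = 0.00124). This window leaves out the positions of the lower peaks, but smaller copy number changes, or tails of the peaks, may lie inside it. Pairs of arrays from different sets of 4 in deposit order, also chosen after the data were seen, gave 0.110 (exact permutation p = 0.00154). Small reference differences below the limit of calling, processing batches that do not follow these sets and an effect of genotype could each give such an excess, and these cannot be told apart because each reference was used with 1 genotype.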
